A study of Mus musculus with 8 samples.

How the data were processed

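RNA of mouse liver was measured by sequencing in 8 C57BL/6 libraries. Of these, 4 came from mice on normal chow and 4 from mice on high-salt chow with 6% NaCl, given for 6 weeks. Per the labels' protocols, livers were flash-frozen on dry ice, RNA was taken with Trizol, and libraries were made with the Illumina TruSeq RNA kit from total RNA. The groups were taken from the diet label of each sample. The titles of the libraries labelled high salt begin with the letter N, which could also be read as normal, and an exchange of the labels would turn every direction printed here. The labels name the groups as mice but do not say that each library came from a separate animal, so p-values measure the spread between these samples, part of which may be technical.

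The authors deposited 1 table of whole-number read counts per gene and library, with no normalization, per the file headers and the values. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.2d, HTSeq 0.6.0 and the genome build GRCm38, with no role for each tool. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of near-identical family members, of genes that share exons and of overlapping genes on opposite strands may therefore be split or pooled in ways the counts do not show. The authors' deposited table also holds, per the file headers, a linear fold change, its log2 value, a p-value and an adjusted p-value for each gene, and the values show that the fold is high salt over normal chow. The tool behind those columns is not given in the sources used here, and they were used only for comparison.

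The table lists 24317 genes, each with at least 1 count. A further line was emptied in the copy used and was not analysed here. In 23 rows the symbol had been turned into a date, and all 23 were restored from the gene ID. There were 30 rows that shared 15 symbols, and these were kept apart by gene ID. Of the gene IDs, 24275 were found in the GENCODE M21 annotation of the same build, 22411 of them with identical coordinates. Coordinates are printed as in the deposited table, counted from 1, in GRCm38.

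Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. The fit used TMM factors, the filterByExpr rule on low counts and a robust quasi-likelihood model of the diet. p-values were adjusted by Benjamini-Hochberg over the 13341 genes that passed the filter. A gene was called at an adjusted p below 0.05, two-sided. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Levels are CPM, counts divided by the TMM-scaled library size in the usual unit of that name. The common biological coefficient of variation was 0.147. Counts were simulated for 13341 genes, with 200 changed genes drawn only from those above a low mean count. A small further list of genes was raised slightly, and calls of its members were counted as true. The edgeR fit recovered 55.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 92.4% of those changed 4-fold, and 6.56% of its 183 calls were false. These rates do not cover genes of low count. In the simulation each gene was drawn on its own, so no rate covers variation that many genes of a library share. DESeq2 1.42.0 recovered 67.2%, 89.6% and 95.5%, with 10.7% of 206 calls false. limma-voom (limma 3.58.1) recovered 47.8%, 86.6% and 95.5%, with 5.20% of 173 calls false.

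Before the data were examined, 50 gene lists for liver metabolism, stress, immunity and cell types were fixed, and the 46 with at least 5 tested members were tested as sets with camera of limma on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. camera with an estimated correlation and fry were fixed as alternatives. The rule for named genes was fixed at the same time. It takes the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM in a group and no overlap between groups, then up to 3 called members of each list, or up to 2 members of smallest p where a list had no called member, and 9 reference genes. Predicted gene models were counted and not named under the rule. Single values of some genes that the rule takes are not reported here, while the gene lists were tested with all their members. Single values, such as library totals and principal component scores, were compared by an exact permutation test over all 70 assignments of the 8 libraries, two-sided, for which the smallest possible p is 0.0286.

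Total counts ran from 16620368 to 18639685 per library. Within a group, chi-square per degree of freedom over genes lay between 9.69 and 36.7 for pairs of libraries. No pair was as close as sampling noise alone would give, and each library was counted as 1 sample. Alternatives covered the normalization (DESeq2 size factors, total counts, upper quartile), the filter (none, or at least 1 CPM in 4 libraries), the test (DESeq2, limma-voom with and without sample quality weights, a fit that is not robust), the threshold, the replicate number as a block, and leaving out each library in turn. A fit without normal chow 1 and high salt 2 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.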

Results

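Liver transcripts were counted in 8 mouse libraries, 4 from C57BL/6 mice on normal chow and 4 from mice on high-salt chow (6% NaCl for 6 weeks). The comparison asks how a high-salt diet changes liver gene expression. Each library held between 16620368 and 18639685 counted reads, and 13341 genes had enough reads to be tested.

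In the livers of the high-salt mice, 4 genes of the fatty acid oxidation list rose. In the urea cycle and nitrogen list 1 gene fell (Got1), and in the amino acid catabolism list 1 gene fell (Tat). Cyp4a10 and Cyp4a14, microsomal omega-hydroxylases of fatty acids and classic targets of the nuclear receptor PPAR alpha, both rose. Cyp4a10 went from 247 ± 23.7 to 522 ± 44.8 CPM and Cyp4a14 from 321.5 ± 106 to 1233 ± 165 CPM (mean ± SD, n = 4 per group). Got1, the cytosolic aspartate aminotransferase, fell from 581.5 ± 61.0 to 307.5 ± 44.1 CPM, and Tat, the first enzyme of tyrosine breakdown, fell from 3438 ± 373 to 2228 ± 88.3 CPM. Cyp2a4, a steroid 15-alpha-hydroxylase that is higher in female liver, fell from 1213 ± 306 to 498 ± 65.3 CPM. By edgeR's quasi-likelihood test, 40 genes changed at an adjusted p below 0.05, 20 higher and 20 lower. Of these, 12 rose and 4 fell by at least 1 on the log2 scale, and 1458 genes had an unadjusted p below 0.05. In all 40 genes the CPM values of the high-salt libraries did not overlap those of the normal-chow libraries, a separation seen in 6.36% of all tested genes and in 2.86% by chance. The 40 genes were called on these same values, so their separation is no added support.

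**Figure D1:**
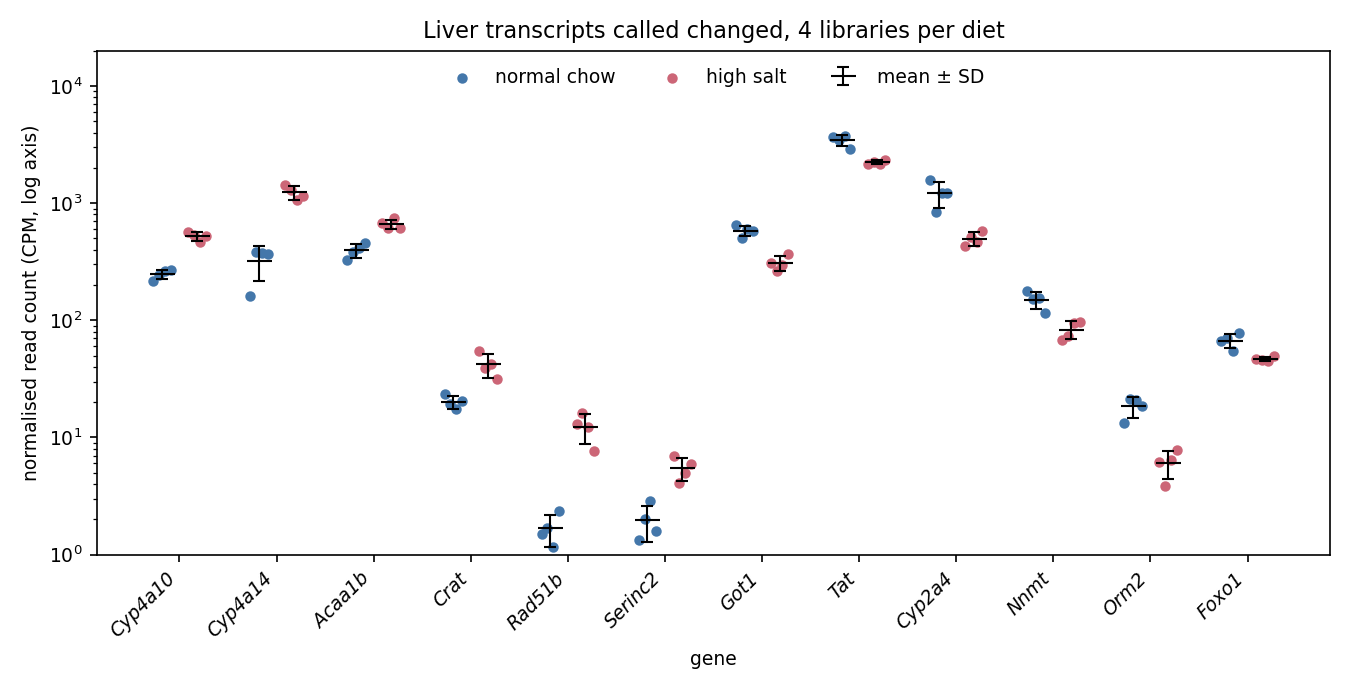
Normalised read counts (CPM, log axis) of 12 called genes, with 1 point per library, normal chow in blue and high salt in red, and black bars for the mean ± SD of 4 libraries. The high-salt points lie above the normal-chow points for Cyp4a10, Cyp4a14, Acaa1b, Crat, Rad51b and Serinc2, and below them for Got1, Tat, Cyp2a4, Nnmt, Orm2 and Foxo1.

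The largest rise among the named genes was that of Rad51b, with a log2 fold change of 2.86 ± 0.26 (SE; adjusted p = 0.00101). Rad51b, on chromosome 12 from 79297282 to 79814690, went from 1.68 ± 0.514 to 12.3 ± 3.56 CPM. Cyp4a14 rose by 1.94 ± 0.27 (adjusted p = 0.0432, called in 1 of the 8 fits that left out 1 library) and Cyp4a10 by 1.08 ± 0.10 (adjusted p = 4.44e-04, called in all 8). These genes lie near each other on chromosome 4, at 115486200 to 115496142 and 115518264 to 115533649. Lrrc39 (2.22 ± 0.36) and Spon2 (1.57 ± 0.27) rose from low levels, 0.275 and 2.13 CPM in normal chow. Serinc2 rose by 1.48 ± 0.24, Casc4 by 1.15 ± 0.18, and Rtn4rl1 by 1.06 ± 0.18. Crat, carnitine acetyltransferase, rose by 1.06 ± 0.16, from 20.1 ± 2.49 to 42.1 ± 9.86 CPM, and the P450 Cyp2j9 by 0.90 ± 0.17. Cyp4a10 has near-identical relatives, so reads may be split within the family. Of these, chosen after their values were seen, Cyp4a32 had 0.87 ± 0.24 (adjusted p = 0.229) and Cyp4a31 0.70 ± 0.49 (adjusted p = 0.675).

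The largest fall was that of Sult1e1, the estrogen sulfotransferase, which fell by 2.53 ± 0.45 on the log2 scale (adjusted p = 0.0387), from a low level of 1.43 ± 0.466 CPM. Orm2, an acute-phase orosomucoid, fell by 1.60 ± 0.21, from 18.4 ± 3.71 to 6.08 ± 1.63 CPM. Cyp2a4 fell by 1.28 ± 0.17 (adjusted p = 0.0192), and Got1 (chromosome 19, 43499752 to 43524605) fell by 0.92 ± 0.11 (adjusted p = 0.00611). Nnmt, which methylates nicotinamide, fell by 0.85 ± 0.15, and the glucuronosyltransferase Ugt1a9 fell by 0.77 ± 0.12. Pptc7, a mitochondrial phosphatase, fell by 0.71 ± 0.11, and Nrg4, a secreted growth factor, fell by 0.71 ± 0.13. Tat (chromosome 8, 109990437 to 109999803) fell by 0.63 ± 0.09 and the sialyltransferase St3gal1 fell by 0.61 ± 0.10. Cyp2a4 has a near-identical relative, Cyp2a5, which had -0.84 ± 0.31 (adjusted p = 0.402, chosen after its values were seen). Ugt1a9 shares exons with the other Ugt1a genes, and Acaa1b, Crat, Lrrc39, Pptc7 and Nrg4 each overlap a gene on the opposite strand. The deposited counts do not show how such reads were assigned.

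Of the 32 tested members of the list of fatty acid oxidation genes and PPAR alpha targets, 4 rose (Cyp4a10, Acaa1b, Crat and Cyp4a14) and 0 fell. Adjusted over the list alone, 17 rose and 0 fell, and 30 of the 32 had a log2 fold change above 0, with a median of 0.33. Acaa1b, a peroxisomal thiolase, rose by 0.74 ± 0.11 (adjusted p = 0.0192), from 395 ± 56.1 to 659 ± 62.3 CPM. Genes that passed over the list alone and not over all genes, chosen after their values were seen, included Fabp1 and Ehhadh. Fabp1, the liver fatty acid binding protein, had 0.50 ± 0.12, and Ehhadh, a peroxisomal bifunctional enzyme, had 0.38 ± 0.12. Pdk4 had a value of the other sign (-0.29 ± 0.13, adjusted p = 0.437, chosen after its values were seen), and Ppara itself had 0.08 ± 0.12 (adjusted p = 0.862). The list lay higher than other genes by camera with the preset correlation (adjusted p = 2.63e-14). The adjusted p = 0.254 with an estimated correlation.

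Lists of amino acid and nitrogen metabolism lay lower than other genes by camera with the preset correlation (adjusted p = 0.214 for both with an estimated correlation). In the amino acid catabolism list, 1 of 37 tested members fell over all genes (Tat), and 14 fell and 1 rose adjusted over the list alone. Its median log2 fold change was -0.23 (camera adjusted p = 4.13e-08). In the urea cycle and nitrogen list, 1 of 15 fell over all genes (Got1) and 7 fell adjusted over the list alone. Its median was -0.38 (camera adjusted p = 3.56e-07). Cps1, which catalyses the first step of the urea cycle, was at 7012 ± 508 CPM in normal chow and 4690 ± 968 CPM in high salt (-0.58 ± 0.13, adjusted p = 0.0946). Ass1 had -0.46 ± 0.11, Asl -0.55 ± 0.12 and Arg1 -0.38 ± 0.10, all 3 chosen after their values were seen. The periportal hepatocyte list, which shares such genes, had 0 of 26 members called by edgeR, 7 lower by DESeq2, 0 by limma-voom and 11 lower at an unadjusted p below 0.05. Adjusted over the list alone, 8 fell, and the median was -0.28 (camera adjusted p = 5.21e-07, and adjusted p = 0.254 with an estimated correlation). Its members of smallest p were Hal, which breaks down histidine (-0.47 ± 0.10, adjusted p = 0.0946), and Cps1.

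Foxo1, a transcription factor of hepatic glucose output, fell by 0.52 ± 0.10 (adjusted p = 0.0432), the 1 called gene of 20 in the gluconeogenesis and glycogen list. Foxo1 was called in 1 of the 8 fits that left out 1 library. Adjusted over the list alone, 4 fell, and the median was -0.23 (camera adjusted p = 0.00206, and adjusted p = 0.214 with an estimated correlation). Of 26 tricarboxylic acid cycle genes, edgeR called 0, DESeq2 called 1 lower, limma-voom called 0, and 6 were lower at an unadjusted p below 0.05. Among them Fh1, fumarate hydratase, had -0.29 ± 0.07 (adjusted p = 0.148). Adjusted over the list alone, 1 fell, and the median was -0.08 (camera adjusted p = 0.00154, and adjusted p = 0.326 with an estimated correlation).

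**Figure D2:**
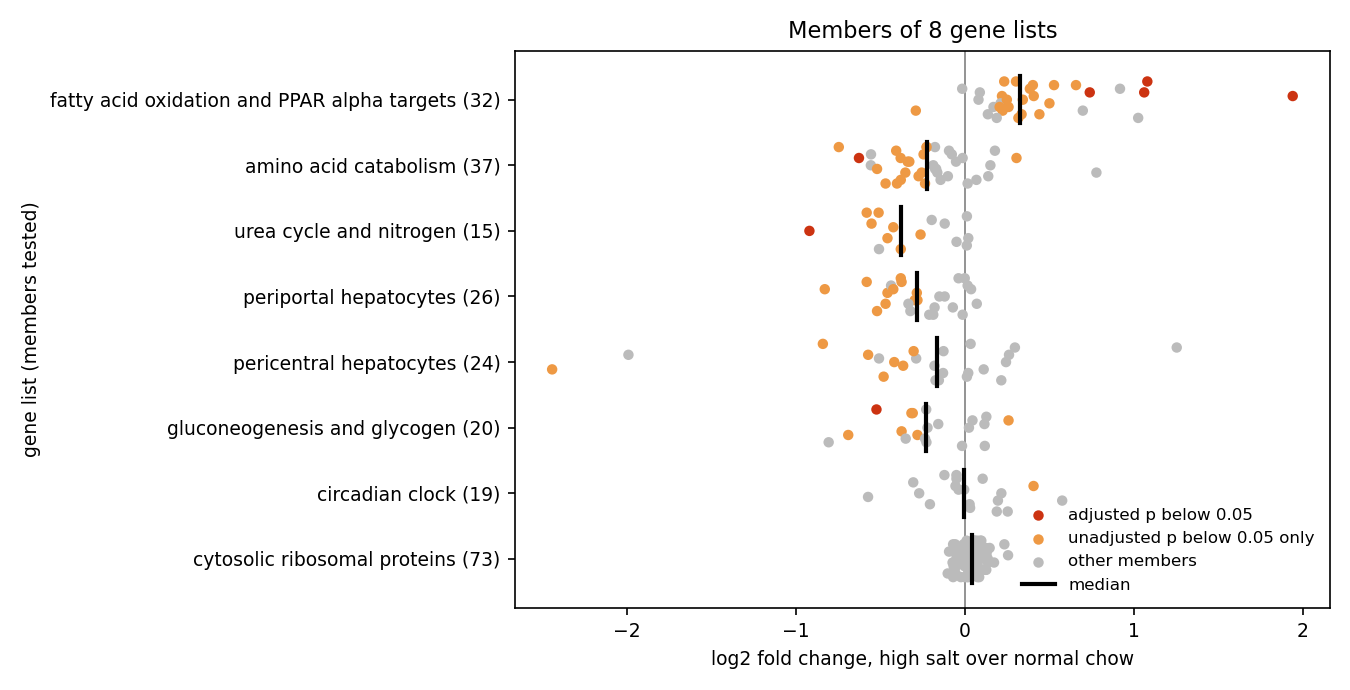
log2 fold change of high salt over normal chow for each tested member of 8 gene lists, 1 point per gene, red for an adjusted p below 0.05 over all genes, orange for an unadjusted p below 0.05 only and grey for the others, with a black bar at the list median. The medians are 0.33 for fatty acid oxidation, -0.23 for amino acid catabolism, -0.38 for the urea cycle, -0.28 for periportal, -0.16 for pericentral and 0.04 for ribosomal protein genes, while that of the circadian clock list changes sign with the scaling.

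The lists of cytochrome P450 genes, conjugating enzymes and female-biased liver genes also lay lower by camera with the preset correlation (adjusted p = 0.400, 0.347 and 0.254 with an estimated correlation). In the cytochrome P450 list, Cyp2a4 was the 1 called gene of 45, 3 fell adjusted over the list alone, and the median was -0.22. By camera the adjusted p = 3.99e-04. Cyp1a1 and Cyp1a2 of that list, chosen after their values were seen, were highest in 1 library. Normal chow 2 had 2019 CPM of Cyp1a1, against 0.587 to 2.76 CPM in the other 7 libraries. Cyp1a2 was at 5640 CPM there, at 643 to 1337 CPM in the other normal-chow libraries and at 321 to 456 CPM in the high-salt libraries. In the list of conjugating enzymes, Ugt1a9 and Sult1e1 fell of 44 tested, 5 fell and 1 rose adjusted over the list alone, and the median was -0.13. For that list the camera adjusted p = 5.61e-05. In the list of female-biased liver genes, Cyp2a4 fell and Cyp4a14 rose of 24 tested, 4 fell and 1 rose adjusted over the list alone, and the median was -0.77. The camera adjusted p = 2.33e-06. Its Cyp3a members have a relative, Cyp3a11, chosen after its values were seen, that was at 1931 ± 424 CPM in normal chow and 3214 ± 901 CPM in high salt (adjusted p = 0.233), and reads may be split between them. Of 23 male-biased liver genes edgeR called 0, DESeq2 2 higher and limma-voom 0, with a median of -0.12 and a mean of 0.03. Slco1a1, an organic anion transporter of that list, had 1.91 ± 0.49 (adjusted p = 0.245). Xist, expressed from the inactive X chromosome, was at 716 ± 50.5 CPM in normal chow and 673 ± 81.8 CPM in high salt (adjusted p = 0.815).

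Among stress and immune genes, Orm2 was the 1 called gene of 30 in the acute phase and complement list, with 2 lower adjusted over the list alone and a median of -0.15. The camera adjusted p = 0.00157, and adjusted p = 0.400 with an estimated correlation. Of 21 heat shock genes edgeR called 0, DESeq2 3 lower and limma-voom 0, with 4 lower adjusted over the list alone and a median of -0.21. The chaperones Hspd1 (-0.34 ± 0.08) and Hsp90ab1 (-0.34 ± 0.09) had the smallest p. For heat shock genes the camera adjusted p = 1.95e-04, and adjusted p = 0.326 with an estimated correlation. Tat was the 1 called gene of 18 in the glucocorticoid and metallothionein list, in which 1 rose and 1 fell adjusted over the list alone, with a median of -0.25. The camera adjusted p = 0.0200, and adjusted p = 0.347 with an estimated correlation. That call ended without normal chow 1 (adjusted p = 0.0649), normal chow 4 (adjusted p = 0.138) or high salt 3 (adjusted p = 0.0890). Of 40 interferon response genes edgeR, DESeq2 and limma-voom each called 0, 0 passed adjusted over the list alone, and 1 was lower at an unadjusted p below 0.05. The median was -0.22 (camera adjusted p = 3.75e-04, and adjusted p = 0.639 with an estimated correlation), and the call ended without high salt 2 (adjusted p = 0.112).

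Marker lists of other liver cells held 1 called gene among those described here, Ehd3, a sinusoidal endothelial marker, which fell by 0.48 ± 0.09 (adjusted p = 0.0438). It was the 1 call of 18 in its list both over all genes and adjusted over the list alone, and the list median was -0.06. The camera adjusted p = 0.00899, and adjusted p = 0.620 with an estimated correlation. It was 0.112 without normal chow 3 and 0.0950 without high salt 3. Of 12 markers of B and plasma cells edgeR, DESeq2 and limma-voom each called 0, 0 passed adjusted over the list alone, and 3 were higher at an unadjusted p below 0.05. The median was 1.23 (camera adjusted p = 0.00154, and adjusted p = 0.620 with an estimated correlation), and the call ended without high salt 2 (adjusted p = 0.0592). Jchain, the joining chain of secreted antibodies, was at 50.6 CPM in high salt 2 and at most 12.9 CPM in any other library.

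Of 14 mitochondrially encoded transcripts edgeR, DESeq2 and limma-voom each called 0, 0 passed adjusted over the list alone, and 1 was lower at an unadjusted p below 0.05. The median was -0.12 (camera adjusted p = 0.0315, and adjusted p = 0.620 with an estimated correlation). The call ended without normal chow 3 (0.0884), normal chow 4 (0.181), high salt 1 (0.108) or high salt 4 (0.170). Of 22 fatty acid and triglyceride synthesis genes each of these tools called 0, 0 passed adjusted over the list alone, and 1 was higher and 3 lower at an unadjusted p below 0.05. The median was -0.22 (camera adjusted p = 0.0315, and adjusted p = 0.639 with an estimated correlation). The call ended without normal chow 3 (0.240) or high salt 2 (0.155).

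The other tested lists were not called by camera. Cholesterol synthesis genes had a median log2 fold change of 0.14, with Fdps, farnesyl diphosphate synthase, at 0.87 ± 0.32 (adjusted p = 0.358). The osmotic stress and NFAT5 list had a median of -0.04, which became 0.02 with total-count scaling. Nfat5, the osmotic response factor, had 0.24 ± 0.10 (adjusted p = 0.431) and Sgk1, a salt-responsive kinase, 0.54 ± 0.16 (adjusted p = 0.216). In the list of ion transport and the renin-angiotensin system, with a median of -0.06, angiotensinogen (Agt) was at 760 ± 29.0 and 630.5 ± 15.1 CPM (-0.27 ± 0.07, adjusted p = 0.186). Extracellular matrix genes had a median of 0.04, Kupffer cell markers -0.06 and pericentral hepatocyte genes -0.16. Of single reference genes that were not called, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.28 ± 0.23 and Pck1, of gluconeogenesis, -0.37 ± 0.10. Srebf1, a regulator of lipid synthesis, had 0.16 ± 0.12, and Alb -0.04 ± 0.07, which became 0.02 with total-count scaling.

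Of the 46 tested lists 17 were called by camera, 0 of them with an estimated correlation and 2 (urea cycle and amino acid catabolism) by fry, and 8 of the 35 splits of the libraries, the diet split included, called at least 17. The count of 40 genes was 4 without normal chow 2, 11 without normal chow 3, 5 without high salt 1 and 18 without high salt 2, and the count of lower genes was 32 without normal chow 1 and 11 with total-count scaling, while DESeq2 called 239 genes and limma-voom 15. Of the 40 genes, only Cyp4a10, Got1 and Rad51b were called in all 8 fits that left out 1 library. Nrg4 and Cyp2j9, like Cyp4a14 and Foxo1, were called in 1 of the 8. Nnmt, Sult1e1, Lrrc39, Rtn4rl1 and Ehd3 were called in 2 of the 8. In the authors' deposited table all 40 genes had an adjusted p below 0.05 and the same direction, among 217 such genes (82 higher and 135 lower). The table marks 52 genes as significant, which also have an absolute log2 fold change of at least 1, and 16 of the 40 are among them. Of those 52 genes, 43 were tested here, of which 27 were not called.

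No measure of the libraries passed a test between the diets. Total counts were 17663200 ± 689200 in normal chow and 17239000 ± 516300 in high salt (exact permutation p = 0.400, n = 4 per group). Mitochondrially encoded transcripts took 8.37 ± 0.171% and 8.04 ± 0.655% of counts (exact p = 0.400). The other measures were the number of genes with a count and the shares of the 10 most abundant genes, of haemoglobin and of ribosomal proteins. The smallest adjusted exact p over the 6 measures was 0.549 by Benjamini-Hochberg. Principal component 1 held 30.9% of the variance, and its mean score was -13.8 ± 14.2 in normal chow and 13.8 ± 16.9 in high salt (exact p = 0.0857, adjusted p = 0.214 over 3 components). Leaving out 1 library gave an unadjusted exact p of 0.0286 without normal chow 1 and of 0.0571 to 0.143 without each of the other 7. High salt 2 had the highest score on component 1 (38.3) and normal chow 1 the lowest on component 2 (-35.2). Neither score exceeded Dixon's critical value within its group, by the ratio described below. Without these 2 libraries, in a fit chosen after seeing the data, 69 genes were called, 26 higher and 43 lower, of which 25 were among the 40.

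**Figure D3:**
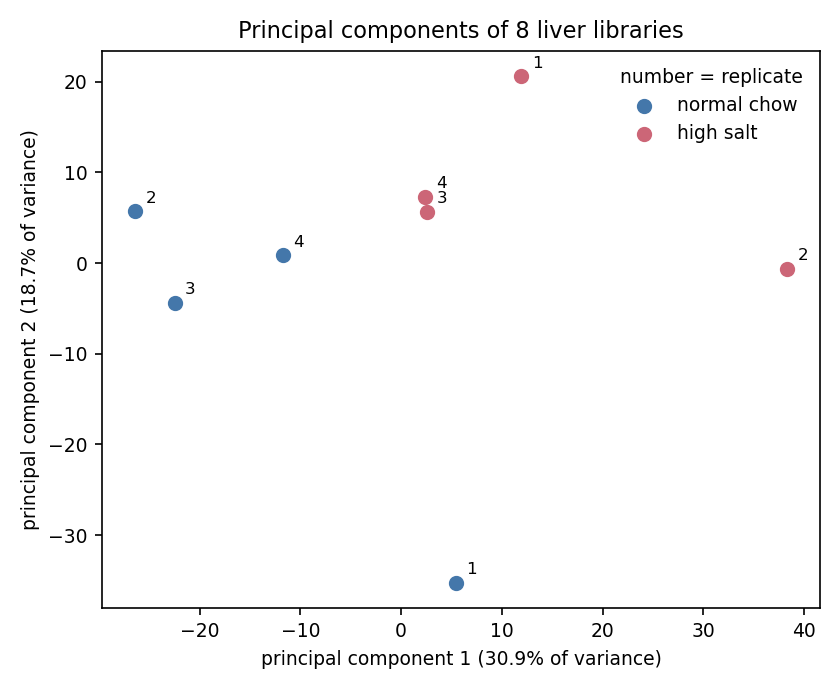
Scores of the 8 libraries on principal components 1 and 2 of log2 CPM, which hold 30.9% and 18.7% of the variance, normal chow in blue and high salt in red, with the replicate number beside each point. High salt 2 lies at 38.3 on component 1 and normal chow 1 at -35.2 on component 2.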

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

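The tests of fasting, cell composition, zonation, sex, paralogs, growth hormone and receptor activation below were chosen only after the result was seen.

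A single library stood apart from the others of its group in 20 of 324 groups of values tested, where chance gives about 1 in 20. The ratio below is the gap to the nearest library over the whole range of the group of 4, and each exceeds Dixon's 95% critical value. Normal chow 1 was lowest for Cyp4a14 (ratio 0.922, 162.5 against 366.7 CPM), Slc1a2 (0.842), Cd163 (0.887) and Cep85l (0.844). It was highest for Ass1 (0.841) and for the share of ribosomal proteins (0.942, 1.52% against 1.25% of counts). Normal chow 2 was highest for Cyp1a1 (0.999), Cyp1a2 (0.861), Xdh (0.874) and Txnrd1 (0.888), and normal chow 4 was lowest for Ugt1a9 (0.896). High salt 2 was highest for Cyp3a11 (0.890, 4559 against 2883 CPM), Gss (0.872) and Jchain (0.841). High salt 3 was highest for Sult2a1 (0.936, 57.2 against 4.52 CPM), Sult2a2 (0.849) and Ndufa9 (0.916). High salt 4 was highest for Lpin1 (0.882) and Pdk4 (0.853) and lowest for Fabp2 (0.839).

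Among the 35 splits of the 8 libraries, 1, the diet split itself, gave as many as 40 changed genes, and the highest other split gave 2. The same held for 20 higher genes (1 split, highest other 2) and for 20 lower genes (1 split, highest other 2), which rest on the same splits. Since 1 of 35 is the smallest share these splits can give, chance is unlikely for these counts but is not excluded. For the 17 gene lists called, 8 splits gave as many and the highest other gave 19, so chance cannot be excluded for the number of lists.

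The fatty acid oxidation list lay higher, and the urea cycle and amino acid lists lower, by camera with the preset correlation, with 4 of 32, 1 of 15 and 1 of 37 members called (adjusted p = 0.254, 0.214 and 0.214 with an estimated correlation). Fasting raises gluconeogenic genes, and the median of that list was -0.228 on the log2 scale, which argues against a longer time without food. Fewer hepatocytes would raise the markers of other liver cells alike, and the pooled median of Kupffer, endothelial and stellate markers was -0.0690, below the rise this would need. More pericentral and less periportal tissue cannot be told apart from a change within cells, since the pericentral median was -0.163 with a spread between libraries too wide to decide. The diet itself stays open as a cause and may act through either.

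The list of female-biased genes lay lower by camera with the preset correlation (adjusted p = 0.254 with an estimated correlation), with 1 of 24 members called lower and 1 higher. RNA of male mice would remove Xist, whose log2 fold change was -0.0877 ± 0.0988 (SE), which argues against it. Of the 5 sex check genes only Xist was among the listed genes, each of which has at least 1 count. The Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty were not listed, which also argues against male RNA. Reads moved between relatives would leave the sum of a whole family in place. The Cyp2a sum was 3535 ± 431 CPM in normal chow and 1927 ± 357 CPM in high salt (mean ± SD, log2 difference -0.886, exact permutation p = 0.0286, n = 4 per group). This argues against moved reads as the whole cause in the Cyp2a family. The sum does not show how much of the fall belongs to Cyp2a4 rather than to its near-identical relative Cyp2a5. A move of reads stays open for the Cyp3a members, whose own sum was 1688 ± 513 and 347.5 ± 350 CPM. The whole Cyp3a sum was 4377 ± 225 and 4324 ± 803 CPM (-0.0336), and Cyp3a11 was at 1931 ± 424 and 3214 ± 901 CPM. For Sult2a (915 ± 233 and 748 ± 171 CPM, -0.278) moved reads cannot be told apart from lower expression. Growth hormone secretion nearer the male pattern, a hypothesis, cannot be told apart from other causes, since the median of male-biased genes was -0.118 with members going both ways.

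Cyp1a1 was at 34892 counts in normal chow 2 and at 10 to 50 in the other 7 libraries. A wrong count in 1 place of the table would leave Cyp1a2 alone, and that gene lay 3.95 SD above the other 7 libraries there. Cyp1a2 was at 5640 CPM there, at 643 to 1337 CPM in the other normal-chow libraries and at 321 to 456 CPM in high salt. Of 6 further targets of the aryl hydrocarbon receptor, 5 were highest there among the 4 normal-chow libraries, 1 of them by a near tie. Activation of the receptor in that sample may account for its high values and stays open, since such genes also vary together for other reasons and no p can be given for it. The targets also lay lower in high salt, in a list chosen after normal chow 2 was seen to be high. All 7 tested targets other than Cyp1a1 had a log2 fold change below 0, and their mean scores did not overlap between the diets. Relative to the normal-chow mean, the score was 0.547 in normal chow 2 and -0.247 to -0.0626 in the other normal-chow libraries. In high salt it was -0.749 to -0.381. Normal chow 2 thus adds to the difference between the diets, and its high values prompted the list. The mean difference was -0.564 ± 0.213 (SE; exact permutation p = 0.0286, the smallest possible and unadjusted, n = 4 per group).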

How the results depend on the processing

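The fit without normal chow 1 and high salt 2 was chosen only after the result was seen. The 40 changed genes (20 higher, 20 lower) became 220 (89, 131) with no filter, 239 (98, 141) with DESeq2, 15 (7, 8) with limma-voom, 16 (8, 8) with its sample quality weights and 19 (11, 8) when the fit was not robust. They became 77 (31, 46) at an adjusted p below 0.1 and 16 (12, 4) with an absolute log2 fold change of at least 1. With total counts the lower genes were 11. Without normal chow 1 and high salt 2 they were 69 (26, 43), with 25 shared. With the replicate number as a block they were 11 (8, 3), of which 8 were shared. The labels of the groups share only that number. Correlations between the groups were taken after the group mean of each gene was subtracted. They were -0.150, -0.195, 0.0865 and 0.00515 for libraries with the same number. For libraries with different numbers they ran from -0.221 to 0.343. Leaving out 1 library gave 4 to 57 changed genes, 2 to 25 higher and 1 to 32 lower. The cause was not tested. The 40 genes gave 758 values over the alternatives, of which 429 were called, 329 were not and 0 reversed. Of 2144 values for 113 other genes, 85 were called and 3 reversed. Alb became 0.021 with total counts. Leaving out 1 library, Des lay between -0.0090 and 0.22. The 17 gene lists became 0 with an estimated correlation and 2 with fry. The difference on principal component 1 was 25.7 to 35.6 when 1 library was left out, with 27.6 in all libraries. Total-count scaling moved the median log2 fold change of all genes to 0.0663, from 0.00596.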

Other observations

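The lists of peroxisomal and mitochondrial fatty acid oxidation genes, the library scores and the neighbouring genes below were tests chosen only after the result was seen.

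Of 17 mitochondrial fatty acid oxidation genes 0 were called, 17 had a log2 fold change above 0, and the mean difference was 0.235 ± 0.0586 (SE; exact permutation p = 0.0286, the smallest possible and unadjusted, n = 4 per group). Of 25 peroxisomal genes 2 were called, 16 had a log2 fold change above 0, and the mean was 0.174 (exact p = 0.0857). The hypothesis that the peroxisomal genes moved more was tested by the difference of the lists, which was -0.0611 ± 0.0442 (exact p = 0.257). This argues against a larger mean change of the peroxisomal list, while the called members of these lists, Acaa1b (0.74) and Crot (0.89), are both peroxisomal.

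Gm15611, a predicted non-coding gene chosen after its values were seen, rose by 3.05 ± 0.39 on the log2 scale (adjusted p = 0.00876). It ends 1077 bases from Crot, the peroxisomal carnitine octanoyltransferase, on the same strand, and Crot rose by 0.89 ± 0.15 (adjusted p = 0.0387). Whether the transcripts are separate was not tested. Among antibody genes chosen after their values were seen, Igkc was at 101 CPM in high salt 2 and 5.10 to 31.7 CPM in the other 7 libraries (adjusted p = 0.486), and Ighm at 129 CPM and 8.34 to 52.8 CPM (adjusted p = 0.462).

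Of 46 fixed lists, 7 had per-library mean scores that did not overlap between the diets (exact permutation p = 0.0286 each, n = 4 per group, and 0.188 by Benjamini-Hochberg). None passed, but 0.0286 is the smallest possible p, and 7 lists at that p are too few of 46 for any to pass. The adjusted test therefore cannot decide. The difference of the mean scores was 0.44 for fatty acid oxidation and below 0 for the other 6: gluconeogenesis -0.20, urea cycle -0.33, amino acid catabolism -0.19, conjugation -0.34, female-biased genes -1.32 and periportal genes -0.25.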
